A study of Mus musculus with 19 samples.

How the data were processed

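RNA was measured by sequencing in 19 libraries of Kupffer cells, the resident macrophages of the liver, sorted from female C57BL/6 mice. Per the labels' protocols, livers were digested with collagenase D, cells were sorted on a FACSAria instrument, RNA was purified with a QIAGEN micro kit, and libraries were made by SMART-seq and sequenced on an Illumina instrument. The groups were taken from the labels. Chow_EmKCs (n = 6) are embryo-derived Kupffer cells of mice on chow, MCD_EmKCs (n = 6) are embryo-derived Kupffer cells of mice fed a methionine- and choline-deficient (MCD) diet for 4 weeks, and MCD_MoKCs (n = 7) are monocyte-derived Kupffer cells of MCD-fed mice. The sort took CLEC2+ TIMD4+ cells as EmKCs and CLEC2+ TIMD4- cells as MoKCs. Nothing in the sources says which libraries come from separate animals, so each p-value measures the spread between samples.

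The authors deposited 1 table of 33919 gene identifiers by 19 libraries. The deposited values are a normalised read signal: within each library the values tested were whole multiples of 1 step, within a tolerance of 0.001 reads, so the values are reads per gene divided by 1 size factor per library. The submitters' processing notes name STAR, DESeq2 and the mouse build mm10, without versions or parameters. The counting tool and the annotation are not given in the sources used here. Dividing by the step recovered the reads. DESeq2 size factors computed from them were 1.0004 to 1.00501 times the deposited scaling. Of the 33919 identifiers, 29062 matched a gene symbol and 4857 did not. Gene positions are those of the GENCODE annotation of the same build. All 19 columns were used.

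The main test was limma (version 3.58.1, R 4.3.3) on log2(value + 1), with a mean-variance trend and robust variance estimates. Genes with a value of at least 10 in at least 6 libraries were tested (14875 genes). All 19 libraries entered 1 model with a mean per group and no covariate, and 3 contrasts were taken, each two-sided with Benjamini-Hochberg adjustment over all genes tested at 0.05. The design written before the data were examined assumed counts and named edgeR's quasi-likelihood test with TMM factors. Because the table holds scaled values, limma took its place, and the edgeR test (version 4.0.16) on the recovered reads was run as an alternative chosen after the unit was known. Log2 fold changes are given with their standard error (SE), and group values are mean ± SD of the deposited signal, here called normalised reads.

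The groups, the comparisons, the first set of alternative settings, the 32 gene lists and the rule for named genes were fixed before the data were examined. The lists comprise 21 programs, 10 sets of markers of other liver and blood cells, and 1 set of genes that respond to cell isolation. Of 539 list entries, 535 were in the table and 499 were tested. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 32 lists within a comparison. They were tested again with an estimated correlation and with fry. Members past the threshold were counted over all genes tested and adjusted over the list alone. The rule named, per comparison, the 5 genes with the highest and the 5 with the lowest fold change (3 and 3 for MCD_MoKCs against Chow_EmKCs) among genes past the threshold. These had to reach a mean of 10 CPM (reads scaled to a common library total) in the higher group and keep their direction in every model that left out 1 library. Predicted genes, mitochondrial genes and immunoglobulin or T cell receptor segments were left out of that part. The rule added up to 3 members, in the direction of the list, of each of the 8 lists with the smallest p past the threshold (4 for MCD_MoKCs against Chow_EmKCs). It added at most 1 member of each other program list, and always the sort genes Timd4 and Clec1b. Other genes named here were chosen after their values were seen, except list members given as examples of a count.

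Total reads, genes detected, the share of reads in the 50 most abundant genes, the mitochondrial share and the share on each other-cell list were compared between groups by exact two-sided permutation tests of the difference of means, adjusted over all 42 tests. The library numbers in the column names run from 17 to 48. Numbers up to 33 and numbers from 37 were taken as separate sets, after the files were seen, and differences were computed again within each. In MCD_MoKCs this cut misses another grouping. Libraries 1 to 3 lay at 38.4 to 86.9 on the third principal component, and libraries 4 to 7 at -75.5 to -25.8. Their mitochondrial shares were 0.534 to 0.729% and 0.244 to 0.359%. The first set joins libraries 4 and 5 with 1 to 3, so differences within the sets do not hold this grouping constant. Total reads ranged from 11642200 to 30983500 per library. Reads carry no molecular identifiers, so counting precision was not computed from them and the spread between libraries was used instead.

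Overlaps of calls between comparisons that share a group were set beside 100 simulations of unchanged groups, beside independent lists, and beside values with the shared group split. Each comparison was also run on 100 splits of its samples, the real one included. The scripts were tested on simulated reads with 200 changed genes. The alternative settings chosen in advance covered DESeq2 (version 1.42.0), edgeR with other scaling factors, edgeR glmTreat against a fold change of 1.5, limma voom with quality weights, no filter, a stricter filter (CPM of 5), the libraries of the groups compared alone, genes detected as a covariate, the replicate number as a block, and leaving out each library. Alternatives added later were edgeR with TMM, pseudocounts of 0.5 and 5, TMM-scaled values, MCD_EmKCs libraries 1 and 2 left out together, the library number as a covariate or as a restriction, the share of reads on the hepatocyte list without Trf, and the share on the sinusoidal endothelial list without Stab2 and Pecam1.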

Results

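RNA was sequenced in sorted Kupffer cells from 6 chow-fed samples of embryo-derived cells (Chow_EmKCs), 6 MCD-diet samples of embryo-derived cells (MCD_EmKCs) and 7 MCD-diet samples of monocyte-derived cells (MCD_MoKCs). The MCD diet, which lacks methionine and choline, is a standard way to induce steatohepatitis in mice. Total reads per library were 19062500 ± 4489750 (SD, n = 6) in Chow_EmKCs, 20239000 ± 3607240 (n = 6) in MCD_EmKCs and 19118300 ± 6233230 (n = 7) in MCD_MoKCs, and ranged from 11642200 to 30983500. Between 14643 and 16847 genes had at least 1 read in a library. The sort gene Timd4 had 10586 ± 2097 normalised reads in Chow_EmKCs, 7491 ± 720.0 in MCD_EmKCs and 400.2 ± 161 in MCD_MoKCs, which the gate sets. Clec1b, which encodes CLEC2, had 6605 ± 804 in Chow_EmKCs, 7000.3 ± 778 in MCD_EmKCs and 5139.6 ± 1068 in MCD_MoKCs.

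The first comparison asks how the MCD diet changed resident, embryo-derived Kupffer cells. In MCD_EmKCs, 12 of 20 lipid-associated macrophage genes and 12 of 23 inflammatory genes rose, as did 7 of 14 genes that respond to cell isolation, and 7 of 12 genes of MHC class II antigen presentation fell. Gpnmb, a transmembrane glycoprotein of lipid-laden macrophages (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929, mm10), rose from 27.4 ± 12.8 to 1329 ± 363 normalised reads (SD, n = 6 and 6). Its log2 fold change was 5.65 (SE 0.34, limma adjusted p = 1.88e-11). Mmp12, the macrophage metalloelastase (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), rose from 242 ± 133 to 11803 ± 3168 (log2 fold change 5.75, SE 0.29, limma adjusted p = 4.97e-12). Of 14875 genes tested, 607 passed the threshold, 372 higher and 235 lower in MCD_EmKCs.

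**Figure D1:**
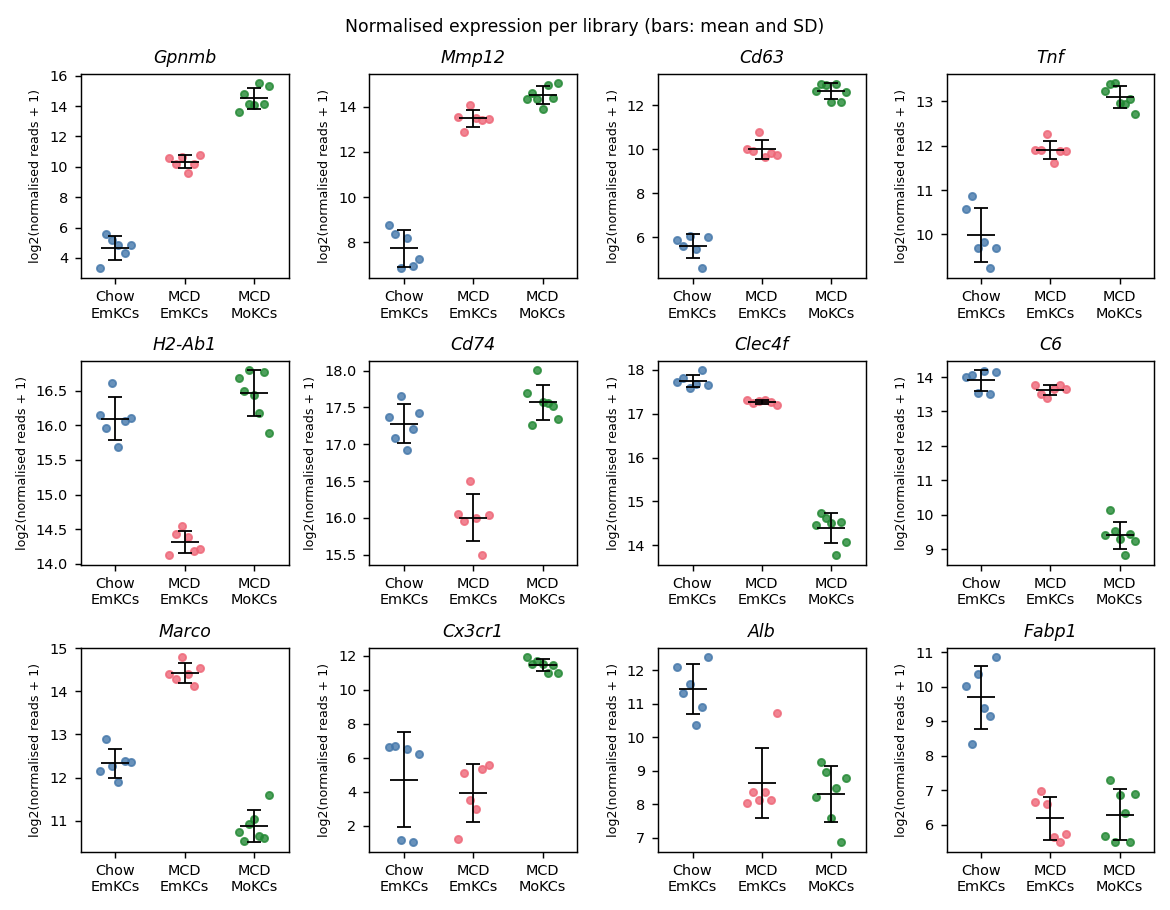
Normalised expression of 12 genes in each of the 19 libraries, as log2(normalised reads + 1) on the vertical axis, by group on the horizontal axis. Points are libraries and bars are the mean and SD. Gpnmb, Mmp12, Cd63 and Tnf step up from Chow_EmKCs to MCD_EmKCs to MCD_MoKCs, and H2-Ab1 and Cd74 are lowest in MCD_EmKCs.

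The lipid-associated macrophage list had 12 of 20 measured members higher and 0 lower in MCD_EmKCs, or 16 higher adjusted over the list alone (camera adjusted p = 9.14e-31). Besides Gpnmb and Mmp12, the tetraspanin Cd63 rose from 49.8 ± 15.7 to 1061 ± 366 normalised reads (log2 fold change 4.40, SE 0.25). The fatty acid receptor Cd36 rose by 2.66 (SE 0.20) and the lipid receptor Trem2 by 1.77 (SE 0.18) on the log2 scale. Of 23 inflammatory cytokine and NF-kB genes, 12 rose and 0 fell, or 16 higher adjusted over the list alone (adjusted p = 8.9e-19). The list of genes that respond to cell isolation rose in the same comparison, as given below, and the share of the inflammatory rise that stems from isolation was not tested. Tnf rose from 1091 ± 485 to 3861 ± 572 (log2 fold change 1.92, SE 0.21). The chemokines Cxcl2 and Ccl4 rose by 1.21 (SE 0.13) and 1.43 (SE 0.16). Of 16 matrix remodelling genes, 5 rose, also 5 adjusted over the list alone (adjusted p = 2.95e-07). Among them, the urokinase receptor Plaur rose by 1.74 (SE 0.17), the membrane protease Mmp14 by 1.78 (SE 0.18) and Mmp19 by 1.37 (SE 0.23).

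The list of MHC class II antigen presentation also includes the costimulatory genes Cd86, Cd80 and Cd40. Of its 12 members, 7 were lower and 0 higher in MCD_EmKCs, or 8 lower adjusted over the list alone (adjusted p = 1.9e-13). H2-Ab1, a class II beta chain (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), fell from 71509 ± 15999.8 to 20456 ± 2332 normalised reads (log2 fold change -1.79, SE 0.15). H2-Eb1 changed by -1.92 (SE 0.17) and the invariant chain Cd74 by -1.27 (SE 0.14). The class II transactivator Ciita changed by -1.61 (SE 0.31). In the NRF2 antioxidant list, 7 of 16 members rose and 1 fell, or 10 and 2 adjusted over the list alone (adjusted p = 8.39e-05). Txnrd1 rose by 0.84 (SE 0.16), Srxn1 by 0.99 (SE 0.20) and Gsr by 0.77 (SE 0.17), while the glutathione transferase Gsta3 changed by -3.38 (SE 0.89).

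Of 18 hepatocyte genes, 11 were lower and 0 higher in MCD_EmKCs, or 17 lower adjusted over the list alone (adjusted p = 2.69e-18). Fabp1 fell from 961 ± 559.8 to 78.0 ± 33.6 normalised reads (log2 fold change -3.50, SE 0.44), Apoa1 changed by -3.15 (SE 0.42) and albumin (Alb) by -2.82 (SE 0.45). The 5 named genes with the lowest fold changes, Plg, Ambp, Adh1, Rgn and F2, are also made mainly by hepatocytes, with log2 fold changes of -5.35, -4.62, -4.51, -4.44 and -4.36. Each had 0 reads in some MCD_EmKCs libraries, so these fitted values depend on the pseudocount. The ratios of the group means were 0.0895, 0.0626, 0.0729, 0.0835 and 0.226, in that order. In MCD_EmKCs, F2 was at 276 normalised reads in library 6 and at most 23.5 in the others. The share of reads on the hepatocyte list was 0.127 ± 0.0175% in MCD_EmKCs and 0.230 ± 0.0418% in Chow_EmKCs (n = 6 and 6, exact permutation p = 0.00216, adjusted p = 0.0114, lower in 6 of 6 samples). The difference was -0.127 percentage points among library numbers up to 33 and -0.0802 among those from 37. Most of the share is Trf, which Kupffer cells also express: it took 0.176 ± 0.0213% of reads in Chow_EmKCs and 0.117 ± 0.0134% in MCD_EmKCs, which is 57.0% of the difference. Without Trf, a measure chosen after the values were seen, the share was 0.00961 ± 0.00732% in MCD_EmKCs and 0.0540 ± 0.0215% in Chow_EmKCs (n = 6 and 6, exact permutation p = 0.00216, lower in 6 of 6 samples), with differences of -0.0514 and -0.0375 percentage points within the sets of library numbers. The calls for Rgn and F2 were lost when single libraries were left out. For Rgn these were Chow_EmKCs 3 and 6 and MCD_EmKCs 2, 3 and 5, with adjusted p from 0.05015 to 0.0647. For F2 they were Chow_EmKCs 1, 2, 3 and 5 and MCD_EmKCs 1, 2 and 5, with adjusted p from 0.0564 to 0.0931.

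The list of genes that respond to cell isolation, immediate-early and heat-shock genes, had 7 of 14 members higher in MCD_EmKCs, or 9 adjusted over the list alone (adjusted p = 2.97e-09). The transcription factors Egr1, Ier2 and Nr4a1 rose by 1.28 (SE 0.15), 0.75 (SE 0.14) and 0.71 (SE 0.15). The unfolded protein list passed with 2 of 17 members higher and 1 lower, or 6 and 1 adjusted over the list alone (adjusted p = 0.00136, but adjusted p = 0.0724 with an estimated correlation). The chaperone Hspa5 and the phosphatase subunit Ppp1r15a rose by 0.53 (SE 0.13) and 0.72 (SE 0.16), and the stress-induced Sesn2 changed by -0.75 (SE 0.20). The lysosome list had 2 of 21 higher, or 4 adjusted over the list alone (adjusted p = 0.00373, and adjusted p = 0.0515 with an estimated correlation), and the sinusoidal endothelial list had 2 of 14 higher, Lyve1 and Bmp2, or 5 adjusted over the list alone (adjusted p = 0.00544, and adjusted p = 0.444 with an estimated correlation). The interferon list had 7 of 22 lower and 1, Cxcl10, higher, or 8 lower and 1 higher adjusted over the list alone (adjusted p = 0.0256, and adjusted p = 0.308 with an estimated correlation). Its adjusted p was 0.105 without Chow_EmKCs 1, 0.0677 without Chow_EmKCs 2 and 0.0597 without MCD_EmKCs 6.

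The other genes with the highest folds were Mrgpre, a G protein-coupled receptor, Ocstamp, a membrane protein of osteoclast fusion, and the sorting receptor Sort1, with log2 fold changes of 7.86 (SE 1.07), 5.59 (SE 0.81) and 5.04 (SE 0.66). Each had 0 reads in some Chow_EmKCs libraries, so these fitted values depend on the pseudocount. The ratios of the group means were 70.1, 15.7 and 20.5. In Chow_EmKCs, Mrgpre was at 101.57 normalised reads in library 6 and at most 2.97 in the others. The Kupffer cell identity list did not pass (adjusted p = 0.445): Folr2, Nr1h3 and Clec4f were lower, and the scavenger receptor Marco rose from 5275 ± 1299.8 to 22315 ± 3624 normalised reads (log2 fold change 2.10, SE 0.18). The monocyte list did not pass either (adjusted p = 0.434), although Itgax, which encodes CD11c, rose by 4.60 (SE 0.44). Among other program lists that did not pass, the amino acid transporter Slc7a5 rose by 5.66 (SE 0.68), Vegfa by 2.75 (SE 0.62), Angptl4 by 1.88 (SE 0.33), Insig1 by 1.04 (SE 0.25) and the cell-cycle inhibitor Cdkn1a by 0.97 (SE 0.20). Slc7a5 had 38 reads in all Chow_EmKCs libraries together and 0 in some, so its fitted value depends on the pseudocount. Its ratio of group means was 32.4. The one-carbon list had a median log2 fold change of -0.03 and a mean of 0.16, and did not pass (adjusted p = 0.302). The mitochondrial share of reads was 0.245 ± 0.0535% in MCD_EmKCs and 0.736 ± 0.211% in Chow_EmKCs (n = 6 and 6, exact permutation p = 0.00216, adjusted p = 0.0114, lower in 6 of 6 samples), with differences of -0.528 and -0.454 percentage points within the sets of library numbers. DESeq2 called 1004 genes. The share on the platelet and megakaryocyte list was 0.00597 ± 0.00116% against 0.00256 ± 0.00112% (n = 6 and 6, exact permutation p = 0.00216, adjusted p = 0.0114, higher in 6 of 6 samples), with differences of 0.00293 and 0.00389 within those sets. Of its 4 genes tested 2, Pf4 and Treml1, were higher, and the list did not pass (adjusted p = 0.0721). Pf4 alone was at 978 ± 276 normalised reads in MCD_EmKCs and 376 ± 166 in Chow_EmKCs, and the share without it was not computed. Within library numbers up to 33 and from 37, with fewer samples, limma called 179 and 263.

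The second comparison asks how monocyte-derived and embryo-derived Kupffer cells differ in MCD-fed mice. Compared with MCD_EmKCs, MCD_MoKCs had lower levels of 18 of 21 Kupffer cell identity genes. They had higher levels of 12 of 17 monocyte, 13 of 20 lipid-associated macrophage and 10 of 12 MHC class II antigen presentation genes. Clec4f, a C-type lectin of Kupffer cells (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187), was at 21839 ± 4644 normalised reads in MCD_MoKCs (n = 7) and 157671 ± 4769 in MCD_EmKCs (n = 6), a log2 fold change of -2.88 (SE 0.12, limma adjusted p = 3.26e-15). Cx3cr1, the fractalkine receptor (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879), was at 2833 ± 665 and 22.8 ± 18.8 (log2 fold change 7.49, SE 0.93, limma adjusted p = 7.94e-06). Of 14875 genes, 1568 passed the threshold, 839 higher and 729 lower in MCD_MoKCs.

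Of 21 Kupffer cell identity genes, 18 were lower and 0 higher in MCD_MoKCs, or 19 lower adjusted over the list alone (adjusted p = 2.12e-34). The complement component C6 was at 703 ± 208 against 12692 ± 1321 normalised reads (log2 fold change -4.21, SE 0.17), and Marco at 1929 ± 569.9 against 22315 ± 3624 (log2 fold change -3.56, SE 0.17). The potassium channel Kcna2 was lower by a log2 fold change of -5.54 (SE 0.54). Of 17 monocyte and recruited macrophage genes, 12 were higher and 1 lower, or 12 and 2 adjusted over the list alone (adjusted p = 2.16e-07). Beside Cx3cr1, fibronectin (Fn1) was higher by 7.37 (SE 0.97) and Itgax by 2.90 (SE 0.42), while Klf2 was at -1.02 (SE 0.20). In MCD_EmKCs, Fn1 was at 297 normalised reads in library 6 and at most 5.84 in the others. The lipid-associated macrophage list had 13 of 20 higher and 1 lower, or 14 and 2 adjusted over the list alone (adjusted p = 1.16e-10). The fatty acid binding protein Fabp5 was at 4005 ± 1813 against 89.2 ± 48.4, Gpnmb at 26061 ± 13188 against 1329 ± 363 and Cd63 at 6550.3 ± 1562 against 1061 ± 366. The collectin Colec12 was the member that was lower, at -2.40 (SE 0.21).

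Of 12 genes of MHC class II antigen presentation, 10 were higher and 1 lower in MCD_MoKCs, also 10 and 1 adjusted over the list alone (adjusted p = 1.15e-11). H2-Ab1 was higher by a log2 fold change of 2.15 (SE 0.14), H2-Eb1 by 2.48 (SE 0.17) and Cd74 by 1.56 (SE 0.14), and the costimulatory Cd86 was at -0.80 (SE 0.21). In the matrix list 6 of 16 were higher, or 8 higher and 1 lower adjusted over the list alone (adjusted p = 6.62e-06), with Plaur at 1.78 (SE 0.17), Mmp14 at 1.22 (SE 0.17) and Mmp19 at 1.21 (SE 0.22). In the inflammatory list 9 of 23 were higher, or 11 higher and 3 lower adjusted over the list alone (adjusted p = 7.4e-05, and adjusted p = 0.0579 with an estimated correlation), with the chemokines Ccl4 at 1.43 (SE 0.16), Ccl3 at 1.57 (SE 0.18) and Cxcl2 at 0.94 (SE 0.13). The cell cycle list had 5 of 29 higher, also 5 adjusted over the list alone (adjusted p = 3.24e-05). Its named members were Rrm2 at 1.87 (SE 0.54), Aurka at 2.43 (SE 0.70) and Top2a at 3.05 (SE 0.87). Their adjusted p was 0.0697 for Rrm2 without MCD_EmKCs 1, 0.0601 for Aurka without MCD_EmKCs 2 and 0.0519 for Top2a without MCD_MoKCs 3.

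**Figure D2:**
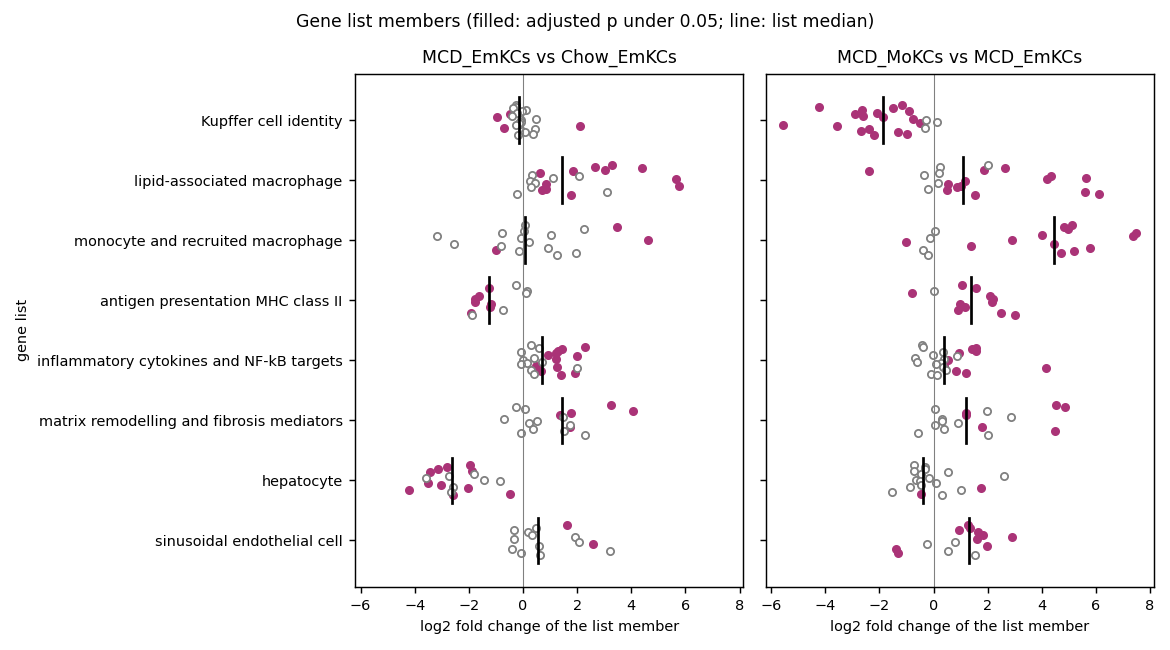
Log2 fold change of each measured member (horizontal axis) of 8 gene lists (vertical axis), for MCD_EmKCs against Chow_EmKCs and MCD_MoKCs against MCD_EmKCs. Filled points passed the limma threshold, open points did not, and vertical lines are list medians. The Kupffer cell identity median is -0.16 in the first panel and -1.88 in the second, and the MHC class II median is -1.24 and 1.37.

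Lists of other metabolic programs also passed, with 5 of 16 NRF2 targets higher (adjusted p = 0.000152), 5 of 17 glycolysis and hypoxia genes higher (adjusted p = 0.000396) and 5 of 21 cholesterol synthesis genes higher (adjusted p = 0.000534). Adjusted over the list alone these were 6, 5 and 7. The other named genes with the highest folds were the surface receptor Cd93 at 8.97 (SE 0.93), coagulation factor X (F10) at 7.50 (SE 0.62) and oncostatin M (Osm) at 7.24 (SE 0.89). In MCD_EmKCs these had 0 reads in some libraries, so the fitted values depend on the pseudocount: the means of normalised reads were 2545 and 19.4 for Cd93, a ratio of 131, with ratios of 107 for F10, 86.8 for Osm and 21.2 for Fn1. The lowest, beside Kcna2, were the transcription factor En2 at -7.06 (SE 0.74), Rims4 at -6.57 (SE 1.00), Klhl29 at -6.18 (SE 0.80) and Fam84a at -5.77 (SE 0.82). En2, Rims4, Klhl29 and Fam84a had 0 reads in some MCD_MoKCs libraries, so their fitted values depend on the pseudocount too. Their ratios of means were 0.0134, 0.0176, 0.0519 and 0.0554. In MCD_MoKCs, Klhl29 was at 92.1 normalised reads in library 4 and at most 3.32 in the others. In program lists that did not pass, the apolipoprotein Apoc1 was lower (-2.85, SE 0.26), as were the desaturase Scd1 (-2.37, SE 0.40), Cpt1a (-1.05, SE 0.22), the mannose receptor Mrc1 (-0.82, SE 0.16) and Irf7 (-0.52, SE 0.14). Psap (1.16, SE 0.15), Fth1 (0.69, SE 0.14) and Cdkn1a (1.28, SE 0.19) were higher.

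Markers of other cells also differed between these groups. Of 12 T and NK cell genes, 6 were higher in MCD_MoKCs, or 11 adjusted over the list alone (adjusted p = 5.25e-07), with Nkg7 at 103 ± 41.4 against 3.81 ± 4.32 normalised reads, Ccl5 at 1.70 (SE 0.31) and Lck at 3.78 (SE 0.95) on the log2 scale. Lck had 0 reads in MCD_EmKCs 1 and 2, so its fitted value depends on the pseudocount. Its means were 118 ± 51.8 and 27.4 ± 43.0 normalised reads, and MCD_EmKCs 6 was at 111. The share of reads on the T and NK cell list was 0.00783 ± 0.00113% in MCD_MoKCs (n = 7) and 0.00189 ± 0.000637% in MCD_EmKCs (n = 6, exact permutation p = 0.000583, adjusted p = 0.00816, higher in 7 of 7 samples). The differences within the sets of library numbers were 0.00603 and 0.00536 percentage points. Within groups, the deviations of these 12 genes correlated with a mean r of 0.00165, at percentile 44.7 of 10000 random lists of genes. They thus showed no sign of rising and falling together, as markers of 1 varying source would. Which cells these reads come from was not tested further. Of 10 dendritic cell genes, 3 were higher, or 5 adjusted over the list alone (adjusted p = 0.00349, and adjusted p = 0.0775 with an estimated correlation). Of 14 sinusoidal endothelial genes, 8 were higher and 2, Stab2 and Pecam1, lower, or 9 and 2 adjusted over the list alone (adjusted p = 0.0149, and adjusted p = 0.427 with an estimated correlation). The share of reads on the platelet and megakaryocyte list was 0.0173 ± 0.00581% in MCD_MoKCs (n = 7) and 0.00597 ± 0.00116% in MCD_EmKCs (n = 6, exact permutation p = 0.00175, adjusted p = 0.0114, higher in 7 of 7 samples), with differences of 0.0126 and 0.00743 percentage points within the sets of library numbers. Of its 4 genes tested, 2 were higher and the list did not pass (adjusted p = 0.0905). Pf4 alone was at 2970 ± 1256 normalised reads in MCD_MoKCs and 978 ± 276 in MCD_EmKCs, while Treml1 was at 0.06 (SE 1.08) on the log2 scale. The share without Pf4 was not computed, so it may reflect that gene rather than platelets. The dendritic cell share was 0.0129 ± 0.00495% against 0.00545 ± 0.00253% (n = 7 and 6, exact permutation p = 0.00932, adjusted p = 0.0356, above all MCD_EmKCs in 5 of 7 samples, 0.00766 and 0.00726 within the sets). The stellate cell and fibroblast share was lower, 0.0172 ± 0.00511% against 0.0263 ± 0.00485% (n = 7 and 6, exact permutation p = 0.0128, adjusted p = 0.0449, below all MCD_EmKCs in 5 of 7 samples, -0.00850 and -0.00989 within the sets). The hepatocyte share was lower as well, 0.0956 ± 0.0126% against 0.127 ± 0.0175% (n = 7 and 6, exact permutation p = 0.00466, adjusted p = 0.0218, below all MCD_EmKCs in 6 of 7 samples, -0.0244 and -0.0326 within the sets). Trf made up 96.1% of that difference, and without it the shares were 0.00840 ± 0.00248% and 0.00961 ± 0.00732% (n = 7 and 6, exact permutation p = 0.864). The endothelial call was lost without MCD_MoKCs 5 (adjusted p = 0.0531) and without MCD_MoKCs 7 (adjusted p = 0.0571). Within library numbers up to 33 and from 37, with fewer samples, limma called 870 and 565 genes.

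The third comparison sets monocyte-derived cells on the MCD diet against resident cells on chow, so that diet and origin differ together. Of 14875 genes, 2493 passed, 1291 higher and 1202 lower in MCD_MoKCs. Lipid-associated macrophage genes were higher in 18 of 20 members (adjusted p = 3.33e-28), with Gpnmb at 9.85 (SE 0.32), Cd63 at 7.05 (SE 0.24) and Mmp12 at 6.77 (SE 0.28) on the log2 scale. Kupffer cell identity genes were lower in 18 of 21 (adjusted p = 6.76e-27), with Clec4f at -3.36 (SE 0.12), C6 at -4.49 (SE 0.17) and Vsig4 at -2.36 (SE 0.13). Inflammatory genes were higher in 16 of 23 (adjusted p = 4.74e-17), with Tnf at 3.12 (SE 0.20), and isolation-response genes in 5 of 14 (adjusted p = 0.000317, and adjusted p = 0.12 with an estimated correlation). Hepatocyte genes were lower in 15 of 18 (adjusted p = 1.34e-11), with Apoa1 at -3.46 (SE 0.41), Fabp1 at -3.40 (SE 0.42) and Trf, which these cells also express at 31684 ± 4404 normalised reads on chow, at -0.97 (SE 0.11). Adjusted over the list alone, these counts were 18 higher and 1 lower, 18 lower, 17 higher and 15 lower. Markers of other cells were also higher in MCD_MoKCs, in 6 of 12 T and NK cell genes (adjusted p = 4.02e-05, and adjusted p = 0.00146 with an estimated correlation) and 3 of 4 platelet and megakaryocyte genes (adjusted p = 0.00832, and adjusted p = 0.0314 with an estimated correlation), or 8 and 3 adjusted over the list alone. Passing only at the preset correlation were 10 of 14 sinusoidal endothelial genes higher and 2 lower (adjusted p = 4.02e-05), 4 of 5 neutrophil genes higher (adjusted p = 0.0175) and 3 of 10 dendritic cell genes higher (adjusted p = 0.0115). In MCD_MoKCs and Chow_EmKCs (n = 7 and 6), the T and NK cell share of reads was 0.00783 ± 0.00113% and 0.00133 ± 0.000325% (exact permutation adjusted p = 0.00816, higher in 7 of 7 samples, 0.00669 and 0.00583 within the sets of library numbers). The platelet and megakaryocyte share was 0.0173 ± 0.00581% and 0.00256 ± 0.00112% (exact permutation adjusted p = 0.0114, higher in 7 of 7 samples, 0.0156 and 0.0113 within the sets). Pf4 alone was at 2970 ± 1256 and 376 ± 166 normalised reads, and the share without it was not computed. The dendritic cell share was 0.0129 ± 0.00495% and 0.00559 ± 0.00183% (exact permutation adjusted p = 0.0343, above all Chow_EmKCs in 5 of 7 samples, 0.00804 and 0.00659 within the sets). The neutrophil share did not pass, at 0.0146 ± 0.00646% and 0.0145 ± 0.00308% (exact permutation adjusted p = 0.988). Nor did the sinusoidal endothelial share, at 0.0739 ± 0.0376% and 0.0529 ± 0.00654% (exact permutation adjusted p = 0.368). The hepatocyte share was 0.0956 ± 0.0126% and 0.230 ± 0.0418% (exact permutation adjusted p = 0.00816, lower in 7 of 7 samples, -0.151 and -0.113 within the sets), and lower without Trf too (exact permutation adjusted p = 0.00816). The MHC class II list did not pass (adjusted p = 0.21), with 2 of 12 members higher and 1 lower, or 3 and 1 adjusted over the list alone. Cd93 and the cystine transporter Slc7a11 had 11 and 7 reads in all Chow_EmKCs libraries together, so their fitted log2 fold changes of 10.38 (SE 0.93) and 9.53 (SE 0.82) depend on the pseudocount. The lowest folds were Rims4 at -6.97 (SE 1.00), Cnpy1 at -6.75 (SE 0.80) and Serpina3k at -6.55 (SE 0.85). Rims4, Cnpy1 and Serpina3k had 0 reads in some MCD_MoKCs libraries, so their fitted values depend on the pseudocount too. The 11 reads of Cnpy1 in MCD_MoKCs all lay in library 1. Within library numbers up to 33 and from 37, with fewer samples, limma called 1257 and 1288 genes.

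In all, 11, 13 and 17 of the 32 lists passed in the 3 comparisons, in the order given, and 7, 10 and 12 with an estimated correlation. With fry, which asks whether the genes of a list move one way on balance and does not compare a list with other genes, 12, 17 and 22 passed. In the third comparison the calls lost were sinusoidal endothelial (adjusted p = 0.143), neutrophil (adjusted p = 0.141), and immediate-early, interferon and dendritic cell genes (adjusted p = 0.12 for each, all with an estimated correlation).

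Comparisons that share a group share its chance values, so overlaps were set beside independent lists, simulated unchanged groups and counts with the shared group split. In total, 102 genes were higher in MCD_EmKCs than in Chow_EmKCs and higher again in MCD_MoKCs than in MCD_EmKCs. Independent lists would give 21.0, and with the MCD_EmKCs libraries split the counts were 69 and 53. Simulated unchanged groups gave 0. Such groups hold almost no genes past the threshold, so a simulated count of 0, here and below, does not measure the overlap. Lower in the first and higher in the second were 38 genes, with 13.3 from independent lists and 19 and 20 after the split. Higher and then lower were 33 genes, with 18.2 from independent lists, and lower in both 17, with 11.5, and simulation gave 0 for each. After the split these were 6 and 11, and 4 and 5. The split fits hold fewer libraries and call fewer genes, so independent lists of their size would give 5.26 and 5.75, and 3.76 and 2.94. For the 102 genes they would give 6.18 and 6.67, and for the 38 they would give 4.41 and 3.42. Both MCD groups were higher than Chow_EmKCs in 293 genes and lower in 165, with 32.3 and 18.99 from independent lists. With the Chow_EmKCs libraries split, the counts were 187 and 151 for higher and 51 and 34 for lower, where independent lists of that size would give 20.1 and 12.1, and 5.99 and 2.78. The covariance of the log2 fold changes against chow was 0.701, where simulation gave 0.211 and the split libraries 0.520 and 0.521.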

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

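All tests of explanations in this part were chosen only after the result was seen, except the splits of the samples, which were planned.

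Hepatocyte transcripts were lower in MCD_EmKCs than in Chow_EmKCs, with a list median of -2.64 on the log2 scale. The scaling of the libraries is argued against as the whole cause, since the median nearest 0 under 4 other scalings was -2.64, and so is the order of the libraries, since the medians within the 2 sets of library numbers were -2.75 and -2.21. A varying amount of hepatocyte RNA in the sorted cells may explain the pattern: the members' deviations within groups correlated with a mean r of 0.173 across genes, at percentile 100 of 10000 random lists. That test is not specific, because 11 of 21 program lists also lay above the 95th percentile, so regulation in the Kupffer cells stays open, as does an effect of the diet on hepatocytes, which was not tested. Whether the sort on CLEC2 and TIMD4 removed whole hepatocytes was not measured. Trf, a member of the list, is abundant in the Kupffer cells themselves. The share of reads on the list was lower without Trf too, with an adjusted p of 0.0114 when it takes the place of the full share among the 42 tests.

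Sinusoidal endothelial transcripts were higher in MCD_MoKCs than in MCD_EmKCs, with a list median of 1.31. The list passed at the preset correlation (adjusted p = 0.0149) but not with an estimated one (adjusted p = 0.427), nor without MCD_MoKCs 5 (adjusted p = 0.0531) or MCD_MoKCs 7 (adjusted p = 0.0571), so the pattern itself is uncertain. Without MCD_EmKCs libraries 1 and 2 the median was 1.08, which argues against those libraries as the cause. A varying amount of endothelial cells or their RNA may contribute, with within-group correlations of mean r 0.390 across genes at percentile 100 of the random lists, a test with the same lack of specificity. The share of reads on the endothelial list did not pass, at 0.0739 ± 0.0376% in MCD_MoKCs (n = 7) and 0.0560 ± 0.0101% in MCD_EmKCs (n = 6, exact permutation p = 0.280, adjusted p = 0.453, above all MCD_EmKCs in 3 of 7 samples). Stab2 and Pecam1 were lower, but Kupffer cells hold them at a high baseline (6019 and 1504 normalised reads on chow), and they made up 65.3% of the share in MCD_EmKCs, so neither they nor the full share exclude anything. Without both, the share was 0.0586 ± 0.0333% and 0.0195 ± 0.00461% (n = 7 and 6, exact permutation p = 0.00758, adjusted p = 0.0312 in place of the full share, above all MCD_EmKCs in 6 of 7 samples). Both genes were left out with their lower values known, which by itself raises the difference, so this does not settle the cause either. Whether the sort on CLEC2 and TIMD4 removed whole endothelial cells was not measured. A difference between cells of different origin stays open and was not tested apart from this.

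MCD_EmKCs libraries 1 and 2 had fewer genes detected, 14643 and 15063, than the other 4 libraries of their group. Total reads leave lower depth open: 1 of the other 4 libraries held fewer reads than the shallower of the pair, but the pair had the lowest size factors of the group, 0.773 and 0.934, and in a first version of this test, which looked at total reads alone, depth had been set aside. A further test thinned the reads of all 6 libraries to the lowest size factor. The higher of the pair then had 14992 genes detected on average and the lower 14643, against 15540.1 to 16055.9 in the other 4, which argues against lower depth as the whole cause. Independent loss or amplification noise in each library may explain the pattern. Their deviations correlated at r = -0.208 across genes, number 8 of the 15 pairs. Centring alone gives -0.2, but only where all libraries of the group vary alike. The pair had the lowest voom quality weights of the group, 0.634 and 0.764 against 0.885 to 1.43. This correlation therefore cannot decide for or against independence. Against independence, the pair lay to the same side on the second principal component, at -142 and -70.6, with the other 4 at -30.5 to -13.9. On the fourth component they lay apart, at -98.7 and 101.8, with the other 4 at -1.04 to 38.6. The pair also shares another feature. Cebpb and Ube2v1 together took 6.15% and 8.13% of their reads, the highest of all 19 libraries, and 1.04% to 2.52% in the other 4 of the group. What links these features to the genes detected was not tested, so the cause stays open. No biological explanation was tested. Without both libraries, 418 genes passed in MCD_EmKCs against Chow_EmKCs and 1154 in MCD_MoKCs against MCD_EmKCs.

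Chance assignment of single libraries is argued against as the source of the counts: of 100 splits in each comparison, 1, the real one, gave as many genes. The splits take each library as independent. Nothing says which libraries come from separate animals, so an effect of libraries that share an animal is not excluded. The real counts were 607, 1568 and 2493, and the highest of the other splits gave 173, 149 and 471.

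Single libraries lay apart from the rest of their group in 18 of 233 groups of values (7.73%), where chance gives about 1 in 20. Total reads were 27401900 in Chow_EmKCs 2, against 15190300 to 19760600 in the others. The share of neutrophil marker reads was 0.0276% in MCD_MoKCs 2, and that of cholangiocyte markers 0.0104% in MCD_MoKCs 5. B and plasma cell markers took 0.0111% and erythroid markers 0.00682% of reads in MCD_EmKCs 3. Normalised reads lay above the rest for Mrgpre in Chow_EmKCs 6 (101.57, others up to 2.97), Cd63 in MCD_EmKCs 3 (1788), Alb in MCD_EmKCs 6 (1704, others up to 330), Mmp19 in Chow_EmKCs 1 (626), Fn1 in MCD_EmKCs 6 (297, others up to 5.84) and Klhl29 in MCD_MoKCs 4 (92.1). They also did for Slc7a11 in Chow_EmKCs 6 (8.17) and Cnpy1 in MCD_MoKCs 1 (18.3), where the others were at 0. They lay below the rest for Ier2 in MCD_EmKCs 1 (13021), Hspa5 in MCD_EmKCs 2 (19263), Angptl4 in Chow_EmKCs 4 (60.6), Aurka in MCD_EmKCs 2 (1.07) and Top2a in MCD_EmKCs 3 (0, others from 56.9).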

How the results depend on the processing

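The edgeR test with TMM, other pseudocounts, TMM-scaled values, the library-number settings the removal of MCD_EmKCs libraries 1 and 2 together, the hepatocyte share without Trf and the endothelial share without Stab2 and Pecam1 were chosen only after the data were seen. The order of comparisons below is MCD_EmKCs against Chow_EmKCs, MCD_MoKCs against MCD_EmKCs, and MCD_MoKCs against Chow_EmKCs, with 607, 1568 and 2493 genes past the threshold. edgeR with TMM called 555, 1324 and 2093. DESeq2 called 1004 in the first, and the cause was not tested. glmTreat, which asks for more than a 1.5-fold change, called 139, 535 and 1024. With fewer samples, library numbers up to 33 gave 179, 870 and 1257 and numbers from 37 gave 263, 565 and 1288. The estimated correlation left 7 of 11 lists in the first comparison. Leaving out 1 library gave 468 to 602, 1288 to 1596 and 2193 to 2456 genes, and 10 to 12, 12 to 15 and 17 to 18 lists. The other settings stayed within 1.5 times. Of 3581 values of named genes under alternatives, 3398 kept their direction and side of the threshold, 176 lost the call, 7 gained one and 0 reversed. Of 2176 list values, 2119 did, 25 lost the call, 32 gained one and 0 reversed. Of 42 tests of library measures, 12 passed on the linear and 12 on the log scale. Without Trf, adjusted p for the hepatocyte share was 0.0114, 0.976 and 0.00816, so the call in the second comparison was lost. Without Stab2 and Pecam1, adjusted p for the endothelial share was 0.0101, 0.0312 and 0.0101, a call gained in each, but both genes were left out with their lower values known.

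The replicate numbers showed no clear pairing of the samples. Deviations of same-numbered libraries correlated at -0.0393 to 0.0759, -0.0743 to 0.0303 and -0.0338 to 0.0575, and 2, 2 and 3 of 6 correlated best with their own number. Their means were 0.0179, -0.0105 and 0.0286, against -0.00343, 0.00176 and -0.00470 for libraries of different number. Only the second comparison lies within 1 diet, so only there could same-numbered libraries share an animal. Other pairings, such as by library number, were not tested. Nothing says whether MCD_MoKCs and MCD_EmKCs libraries come from the same mice, and the second comparison treats them as independent. With the replicate number as a block, 608, 1658 and 2474 genes and 13, 14 and 18 lists passed. On simulated reads of 14875 genes, the test recovered 22, 21 and 21 of 100 genes changed by 1 on the log2 scale and 59, 68 and 65 of 100 changed by 2, and it called 2, 8 and 4 unchanged genes, so smaller changes were often not detectable at this depth and number of samples.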

Other observations

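The genes and sets in this part were chosen only after their values were seen. Gdf15, a stress-induced cytokine, rose in both steps: it had 582 ± 77.3 normalised reads in Chow_EmKCs (n = 6), 5949 ± 394 in MCD_EmKCs (n = 6) and 16182 ± 1529 in MCD_MoKCs (n = 7), with limma log2 fold changes of 3.36 (SE 0.12) for the diet and 1.44 (SE 0.12) between the MCD groups. Il1rn, the interleukin-1 receptor antagonist, rose by 1.99 (SE 0.18) and then 0.67 (SE 0.17), and the transcription factor Egr2 by 2.98 (SE 0.27) and then 1.06 (SE 0.26). Cd207, which encodes langerin, went from 9100.1 ± 1035 in Chow_EmKCs to 2532 ± 369.8 in MCD_EmKCs and 4006 ± 901 in MCD_MoKCs. Of 8 mitochondrially encoded protein genes tested, 7 were lower in MCD_EmKCs than in Chow_EmKCs, with a median log2 fold change of -1.45. In MCD_MoKCs, 6 were lower than in Chow_EmKCs (median -0.887), and 1 was higher than in MCD_EmKCs (median 0.604).

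Genes that set MCD_MoKCs apart from MCD_EmKCs included the chemokine receptor Ccr1 at 1075 ± 109 against 35.4 ± 42.6 normalised reads, the C-type lectin Clec4e at 3384 ± 1183 against 197 ± 70.6, and coagulation factor VII (F7) at 547 ± 270.0 against 20.7 ± 39.3. The B cell chemokine Cxcl13 was at 274 ± 128 against 3044 ± 579.8, and complement C4b at 1663 ± 535 against 12790.3 ± 3199.9.

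Cebpb ranged from 62722 to 1055040 normalised reads over the 19 libraries, with its highest values in MCD_EmKCs 1 and 2 (813792 and 1055040), and together with Ube2v1 it took up to 8.13% of a library's reads. Ube2v1 stood at 0.696 to 0.813 times Cebpb in every library. The counting tool and the annotation behind the table are not given, so whether reads are shared between genes is not known, and the values of Ube2v1 and Ddx3y are uncertain. In the annotation these 2 genes do not overlap, with Cebpb at chromosome 2, 167688915 to 167690418, and Ube2v1 at 167607638 to 167632095. However, Tmem189, at 167642608 to 167689822 on the strand of Ube2v1, lies between them and overlaps Cebpb. The positions therefore do not exclude shared reads. Neither Cebpb nor Ube2v1 passed between groups, with limma adjusted p of 0.454 for Cebpb and 0.404 for Ube2v1 in MCD_EmKCs against Chow_EmKCs. Ddx3y, a gene of the Y chromosome, had 162 to 695 normalised reads in every library of these female mice, while Uty, also Y-linked, had reads in 5 libraries (up to 16.1), Kdm5d and Eif2s3y had 0 in all 19 and Xist had 657 to 2472.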
